A study of Mus musculus with 6 samples.

How the data were processed

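The series holds 6 RNA-seq libraries of sorted mouse spleen cells, labelled as macrophages, 3 Qtracker positive and 3 Qtracker negative, sequenced on one instrument type. Per the labels' protocols, labelled human MSCs were plated, T cell-depleted splenocytes were added and cultured for 3 days, and cells were stained, sorted and lysed, with RNA from a column kit and libraries from a stranded kit. Whether the counting used strand is not given in the sources used here.

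The deposited raw table holds estimated counts per gene as whole numbers for 21847 genes, and the submitters' processing notes name FastQC, Salmon and the mm10 build without versions. Salmon estimates need not be whole, so the deposited expected counts are rounded values. The annotation release is not given in the sources used here. The deposited normalized table holds a signal that is the raw count multiplied by a factor that differs by gene and library, and the authors' formula is not stated. It was used only as an alternative. Of the gene identifiers, 21625 were found in the GENCODE M21 annotation (the same mouse assembly as mm10), which filled 5210 missing symbols and gave the gene coordinates. A further 18 duplicate symbols were replaced by identifiers, and 237 genes had no symbol.

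Genes were kept by filterByExpr (minimum count 10, minimum total 15), which left 14605, and scaled by TMM. The test was the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3 with replicate number as a block, and genes were called at a Benjamini-Hochberg adjusted p under 0.05. Standard errors were derived from the F statistic. CPM were computed here on the TMM-scaled totals, with a prior count of 2 for log2 values. Library totals were 33943090 to 55506993 counts. Over genes with 500 to 2000 counts, the variance between replicate 1 and the others was 38.5 to 116 times that of counting, so for these genes the spread between replicates, more than depth, limited the precision.

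Before the data were examined, 36 gene lists were fixed. They were tested with camera in limma 3.58.1, with the preset correlation of 0.01 and again with an estimated correlation. With the estimate 0 lists were called (smallest adjusted p = 0.57). That version rests on the residual degrees of freedom, which are few with 6 libraries and a block, so it can call little. It lost even the eosinophil, basophil and mast cell list, whose estimate was -0.0498 (camera p 0.000149, then 0.0541). Its lost calls therefore do not decide whether correlation explains a call. The preset may still be too low for lists such as cholesterol synthesis (estimate 0.982). Fry, which asks whether a set's genes move one way on balance and does not compare them with other genes, had an adjusted p under 0.05 for 16 lists. Some lists called by camera were not among them. Their adjusted p by fry was 0.0529 for scavenger receptors and 0.0541 for complement, chemokines and oxidative phosphorylation. It was 0.0799 for unfolded protein stress, 0.105 for proliferation and 0.167 for cholesterol synthesis. Named genes were also fixed by rule: the 8 largest rises and 8 largest falls among called genes that changed alike in all 3 pairs with mean log2 CPM of at least 3 and an established symbol, the 2 lowest p-values of each list with at least 5 measured members, and a set of fixed genes. A gene of the monocyte list that the rule names is not reported here. Epx, Ear1, Fdps, Scd1, Scd2, Spic, Vcam1, Slc40a1, Pecam1, S100a9 and Ighm are named outside that rule and were chosen after their values were seen.

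The pairing was taken from the series' design text, which calls the replicates paired. The deviations of same-numbered libraries from their group means correlated at 0.2, 0.077 and 0.16 across genes, and the highest correlation with another number was -0.11, 0.15 and 0.12, so the data alone did not establish the pairs.

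The pipeline was tested on simulated data with 14345 genes tested and 100 genes changed at each of 2 fold sizes. Each gene had the same fitted dispersion in all libraries, with a random pair effect. No replicate stood apart as replicate 1 did in the data, and far fewer genes were changed than were called in the data. The rates below therefore do not give the power or the false calls of the real fit. At 2-fold 0 of 100 and at 4-fold 32 of 100 changed genes were called, with 1 unchanged gene called. The changed list was called, and 0 of 20 null lists were. The null lists were random genes simulated independently. They therefore do not test the preset correlation on lists whose genes move together.

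Alternatives covered median-of-ratios, upper quartile and no composition scaling, no filter, a stricter filter (50 counts in 3 libraries), DESeq2 1.42.0, limma-voom, the authors' normalized counts on the log2 scale with a pseudocount of 1, no replicate block, each replicate left out, and replicates 2 and 3 summed. Figures were drawn with matplotlib 3.10.9.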

Results

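RNA was sequenced from sorted mouse spleen cells, labelled as macrophages, that had been cultured for 3 days with human mesenchymal stromal cells (MSCs) from cord tissue. The MSCs carried Qtracker, a fluorescent quantum dot label, and splenocytes depleted of T cells were added to them. Sorted cells that held the label, which the series takes to have engulfed MSCs, were compared with sorted cells that did not. Each group, Qtracker positive and Qtracker negative, had 3 libraries, and the series describes them as paired biological replicates. The design asks how the RNA of macrophages that engulf MSCs differs from that of macrophages that do not. The labels give the gate as CD11b positive and Ly6G negative in one place and as Ly6C negative in another, so the exact gate is uncertain.

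Total estimated counts were 33943090, 42259316 and 44061187 in Qtracker negative replicates 1, 2 and 3, and 42490705, 55506993 and 53656135 in Qtracker positive replicates 1, 2 and 3. The first principal component of log2 CPM (counts scaled to a common library total) held 68.4% of the variance and separated the groups, and the second held 17.4% and separated replicate 1 from replicates 2 and 3. Replicates 2 and 3 were close to each other. Over genes with 500 to 2000 counts, their median absolute log2 difference was 0.0549 in the negative group and 0.0821 in the positive group. The corresponding differences between replicate 1 and the others were 0.462 to 0.465 and 0.272 to 0.28. The spread between replicates 2 and 3 was 1.66 times (negative) and 3.69 times (positive) the counting variance, so it exceeded sampling noise. Replicates 2 and 3 were kept as separate libraries, although this spread does not show that they are independent. The labels do not say whether they came from separate animals, so p-values measure the spread between these libraries, which may be partly technical.

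**Figure D1:**
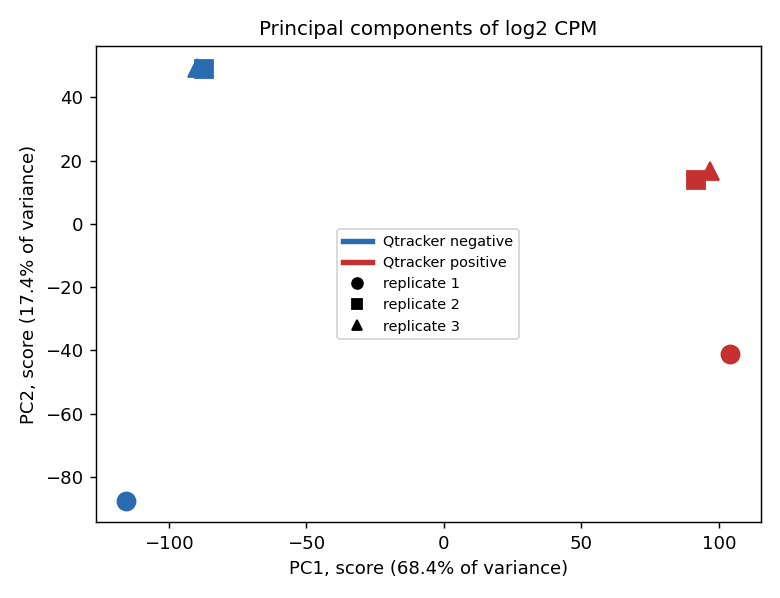
Scores of the 6 libraries on the first and second principal components of log2 CPM, with the groups in colour and the replicates as symbols. The groups separate along the first component (68.4% of variance), and replicate 1 of each group lies apart from replicates 2 and 3 along the second (17.4%).

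Lipid-binding, growth factor and lysosomal genes were among the largest rises in Qtracker positive libraries, and neutrophil genes among the largest falls. Fabp4, a fatty acid binding protein on chromosome 3 from 10204088 to 10208576 (mm10), rose from 1.13 ± 0.513 to 129 ± 44.3 CPM (SD, n = 3), a log2 fold change of 6.87 ± 0.15 (standard error). Igf1, a growth factor on chromosome 10 from 87858265 to 87937042, rose from 0.764 ± 0.178 to 79.9 ± 20.02 CPM, by 6.70 ± 0.20 on the log2 scale. The other 6 of the 8 largest rises among genes with mean log2 CPM of at least 3 were Pmp22 (6.48), C77080 (6.08), the amino acid transporter Slc36a2 (6.00), the proton pump subunit Atp6v0d2 (5.98), the glutathione transferase Gstm2 (5.98) and the protease Ctsk (5.81). The 8 largest falls by the same rule were Mrgpra2b (-7.78), Tinagl1 (-7.58), Ly6g (-7.36), Olfm4 (-6.99), Ankrd22 (-6.83), Crispld2 (-6.82), Ceacam10 (-6.63) and Ltf (-6.59). Ly6g, on chromosome 15 from 75155240 to 75159126, and Ltf, the lactoferrin of neutrophil granules on chromosome 9 from 111019271 to 111042767, are neutrophil genes. Mrgpra2b belongs to a family of near-identical copies, so its count is uncertain. Adjusted p by edgeR's quasi-likelihood test ran from 0.00585 to 0.0293 over these 16 genes.

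Of 14605 genes tested, 2707 were higher and 2384 lower in Qtracker positive cells (edgeR quasi-likelihood test with replicate as a block, Benjamini-Hochberg adjusted). By at least 2-fold, 1687 and 1938 of them were. In all, 34.9% of tested genes were called, the share against which each list's members called over all genes should be read. It is not the background for the counts adjusted over a list alone, whose cutoff differs by list. Of all tested genes, 7348 had an unadjusted p under 0.05 by the edgeR test. With library totals alone as scaling, which shifted the median of all tested genes to -0.357 on the log2 scale from -0.0105, 32.2% of the calls were higher instead of 53.2%. The counts depended on which replicates were used. Without replicate 1, 5538 genes were higher and 5352 lower. Without replicate 2, 136 and 175 were. Without replicate 3, edgeR called 0, with 4209 genes at an unadjusted p under 0.05, while DESeq2 called 3242 and limma-voom 1167. With replicates 2 and 3 summed into 1 library per group, a setting added after the data were seen, edgeR called 0, with 4488 genes at an unadjusted p under 0.05, DESeq2 3543 and limma-voom 1405. Of 36 gene lists 13 were higher and 9 lower by camera with its preset correlation, and 0 with an estimated correlation. The latter version has too few residual degrees of freedom here to decide. Some lists called by camera did not reach an adjusted p under 0.05 by fry. They were the scavenger receptor, complement, chemokine, oxidative phosphorylation, unfolded protein, proliferation and cholesterol synthesis lists. Among the 91 named genes, 54 lost their call without replicate 2, and 87 lost their call without replicate 3 and with replicates 2 and 3 summed.

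**Figure D2:**
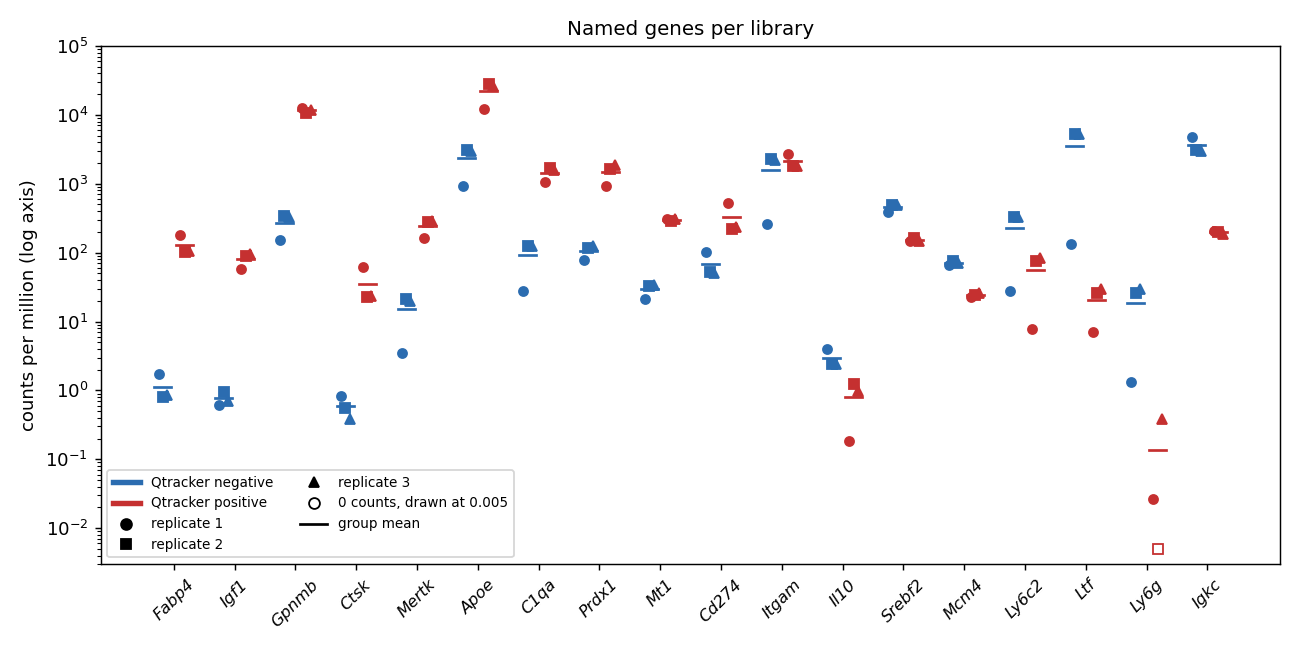
CPM of 18 named genes in each library on a log axis, with group means as lines, groups in colour and replicates as symbols. Fabp4, Igf1, Gpnmb and Ctsk are higher in each Qtracker positive library than in each negative one, and the Itgam value of Qtracker negative replicate 1, 259.6 CPM, lies far below those of the other 5 libraries.

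Among the genes of the gate, Itgam, which encodes CD11b, did not pass the test, with a log2 fold change of 0.79 ± 1.00 and adjusted p = 0.565. It stood at 259.6 CPM in Qtracker negative replicate 1 and at 2269 and 2211 CPM in replicates 2 and 3, so its change was 3.39 in pair 1, -0.32 in pair 2 and -0.27 in pair 3. Adgre1, which encodes the macrophage marker F4/80, rose from 159 ± 59 to 881 ± 172 CPM (SD, n = 3). Ly6c2 fell from 229 ± 174 to 55 ± 41 CPM, a call that was lost without the replicate block (adjusted p = 0.193). Although the gate named Ly6G, Ly6g RNA was 18.8 ± 15.2 CPM in the negative group and 0.136 ± 0.212 CPM in the positive group, with 1 positive library at 0. Of the 7 measured gate and lineage genes 1 rose and 5 fell, also adjusted over the list alone. The list was not called (camera adjusted p = 0.0652), but was lower in 5 alternatives (0.0167 to 0.036), among them without replicate 2 (0.0304) and without replicate 3 (0.0237).

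Most measured markers of B cells, NK cells, T cells and neutrophils were lower in Qtracker positive libraries. Of 20 measured B cell genes 18 fell (20 adjusted over the list alone), including the antibody chain genes Jchain (-4.50 ± 0.14) and Igkc (-4.16 ± 0.26), whose reads may be shared with related segments. The list was lower by camera (adjusted p = 2.24e-09; adjusted p = 0.579 with an estimated correlation), with a median log2 fold change of -4.61 in pair 1, -2.57 in pair 2 and -2.82 in pair 3. Of 16 NK cell genes 12 fell (15 adjusted over the list alone), including the interleukin receptor chain Il2rb (-4.28 ± 0.25) and the granzyme Gzmb (-5.09 ± 0.32, adjusted p = 0.0711 without the block). Of 19 T cell genes 15 fell and 1 rose (17 and 1 adjusted over the list alone), including Tcf7 (-4.06 ± 0.23) and Thy1 (-3.52 ± 0.23). Camera adjusted p was 3.66e-07 for the NK list (adjusted p = 0.567 with an estimated correlation) and 2.94e-06 for the T cell list (adjusted p = 0.579 with an estimated correlation). Without replicate 1, neither list was called (0.118 and 0.337), although 14 of 15 NK and 15 of 18 T cell genes were lower, with medians of -4.048 and -2.333. Of 19 neutrophil genes 14 fell (15 adjusted over the list alone), with camera adjusted p = 7.12e-07 and adjusted p = 0.579 with an estimated correlation. The median of the list was -3.36 in pair 1, -6.44 in pair 2 and -6.32 in pair 3, and Ltf stood at 134.8 CPM in Qtracker negative replicate 1 and at 5326 and 5244 CPM in replicates 2 and 3. Retnlg fell by 5.82 and Stfa2, of a family of near-identical copies, by 3.94.

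Granulocyte and dendritic genes moved in both directions. Of 19 eosinophil, basophil and mast cell genes, 13 fell and 4 rose (15 and 4 adjusted over the list alone). The 4 that rose were the eosinophil granule genes Prg2 (2.68 ± 0.15), Ear6 (3.85 ± 0.22), Epx (3.81) and Ear1 (3.59), where the Ear copies are nearly identical. The list was lower by camera (adjusted p = 0.000383; adjusted p = 0.567 with an estimated correlation). Of 19 dendritic cell genes 11 fell and 3 rose (11 and 4 adjusted over the list alone), among them the receptor Flt3 (-3.50 ± 0.23), with camera adjusted p = 0.0148 (adjusted p = 0.567 with an estimated correlation) and 0.102 without replicate 1. It also missed the threshold with library totals alone (0.0812). Of 21 monocyte genes 8 fell and 1 rose, the same numbers adjusted over the list alone, with camera adjusted p = 0.0261 (adjusted p = 0.579 with an estimated correlation) and 0.0553 with library totals alone. Erythroid and megakaryocyte genes split, with 3 of 12 higher, including Vwf (3.60 ± 0.20), and 3 lower, including Car2 (-2.99 ± 0.32), also adjusted over the list alone, and the list was not called (adjusted p = 0.757). Of 6 endothelial and splenic stroma genes, 1 rose, Kdr (4.40 ± 0.50), and 2 fell, including Egfl7 (-2.57 ± 0.31) (1 and 4 adjusted over the list alone), and the list was not called (adjusted p = 0.109), but was lower with no filter (0.0168).

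Lysosomal genes formed the list with the lowest camera p. Of 38 measured members 32 rose and 0 fell (36 adjusted over the list alone), with a median log2 fold change of 2.59. Gpnmb, a glycoprotein of lysosomes and melanosomes, rose from 269.9 ± 103 to 11580 ± 969 CPM, and Ctsk from 0.591 ± 0.221 to 35.6 ± 22.2 CPM. The list was higher by camera (adjusted p = 1.69e-15; adjusted p = 0.567 with an estimated correlation). Of 22 scavenger and pattern receptors 13 rose and 0 fell (16 adjusted over the list alone), including the mannose receptor Mrc1 (4.79 ± 0.36), the lectin Clec10a (3.04 ± 0.18), the lysosomal receptor Scarb2 (1.82 ± 0.14) and Trem2 (3.82 ± 0.74). Of 19 receptors and bridging molecules for apoptotic cells 11 rose and 3 fell (12 and 3 adjusted over the list alone). The kinase receptor Mertk rose by 4.32 ± 0.50, its relative Axl by 3.18 ± 0.39, their ligand Gas6 by 5.55 ± 0.23 and the bridging protein Mfge8 by 2.08 ± 0.12. Camera adjusted p was 1.56e-06 for the scavenger list (adjusted p = 0.579 with an estimated correlation) and 0.000484 for the apoptotic cell list (adjusted p = 0.615 with an estimated correlation). Over pairs 1, 2 and 3 the median was 3.78, 1.91 and 1.96 for the scavenger list and 3.77, 1.94 and 1.97 for the apoptotic cell list. Pair 1 was also where Itgam rose (3.39, against -0.32 and -0.27). The B cell list fell most there (-4.61, against -2.57 and -2.82), and the neutrophil list fell least (-3.36, against -6.44 and -6.32). In complement, 7 of 13 members rose (8 adjusted over the list alone), including C1qa, a chain of the first component, at 4.21 ± 0.46, and C4b at 2.96 ± 0.32, whose call was lost without the block (adjusted p = 0.128). That list had camera adjusted p = 0.000444 (adjusted p = 0.615 with an estimated correlation).

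Lipid handling genes were also higher. Of 29 members of the cholesterol efflux and lipid storage list 13 rose and 2 fell (16 and 2 adjusted over the list alone), with camera adjusted p = 0.000125 (adjusted p = 0.567 with an estimated correlation). Fabp5, a fatty acid binding protein, rose from 68.4 ± 4.87 to 3405 ± 289 CPM, and the lipid carrier Apoe from 2350 ± 1222 to 22294 ± 8654 CPM. The list also holds Spp1, or osteopontin, not itself a lipid handling protein, which rose from 382 ± 34.5 to 8027 ± 3704 CPM. The 2 members that fell were Scd1 (-3.38) and Scd2 (-1.16), and 14 did not pass. Of 20 cholesterol synthesis genes 3 fell and 0 rose, the same numbers adjusted over the list alone. Without replicate 1 all 20 fell, a setting in which 5352 of 14932 tested genes fell. The 3 were the mevalonate pathway enzymes Pmvk (-1.59 ± 0.12) and Fdps (-2.17) and Srebf2, the regulator of the pathway (-1.59 ± 0.14). The list was lower by camera (adjusted p = 0.000513; adjusted p = 0.672 with an estimated correlation), with a median of -0.08 in pair 1, -1.64 in pair 2 and -1.59 in pair 3, and the neutrophil list likewise fell less in pair 1 (-3.36) than in pairs 2 and 3 (-6.44 and -6.32). Of 21 red pulp macrophage and iron recycling genes 14 rose and 1 fell (15 and 1 adjusted over the list alone), including the liver X receptor Nr1h3 (3.94 ± 0.20) and Gdf15 (5.73 ± 0.12), with camera adjusted p = 1.78e-06 (adjusted p = 0.567 with an estimated correlation). Nr1h3 also stood on the lipid list and Gdf15 on the trophic list. The 6 that did not pass the edgeR test included Spic (1.87, adjusted p = 0.112), Vcam1 (-0.39, 0.516) and Slc40a1 (0.53, 0.367). The 1 that fell was Pecam1 (-2.91). The list call therefore does not show a gain of red pulp identity. Of 14 trophic factors 11 rose and 1 fell (12 and 1 adjusted over the list alone), led by Igf1, with camera adjusted p = 5.82e-06 (adjusted p = 0.567 with an estimated correlation).

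**Figure D3:**
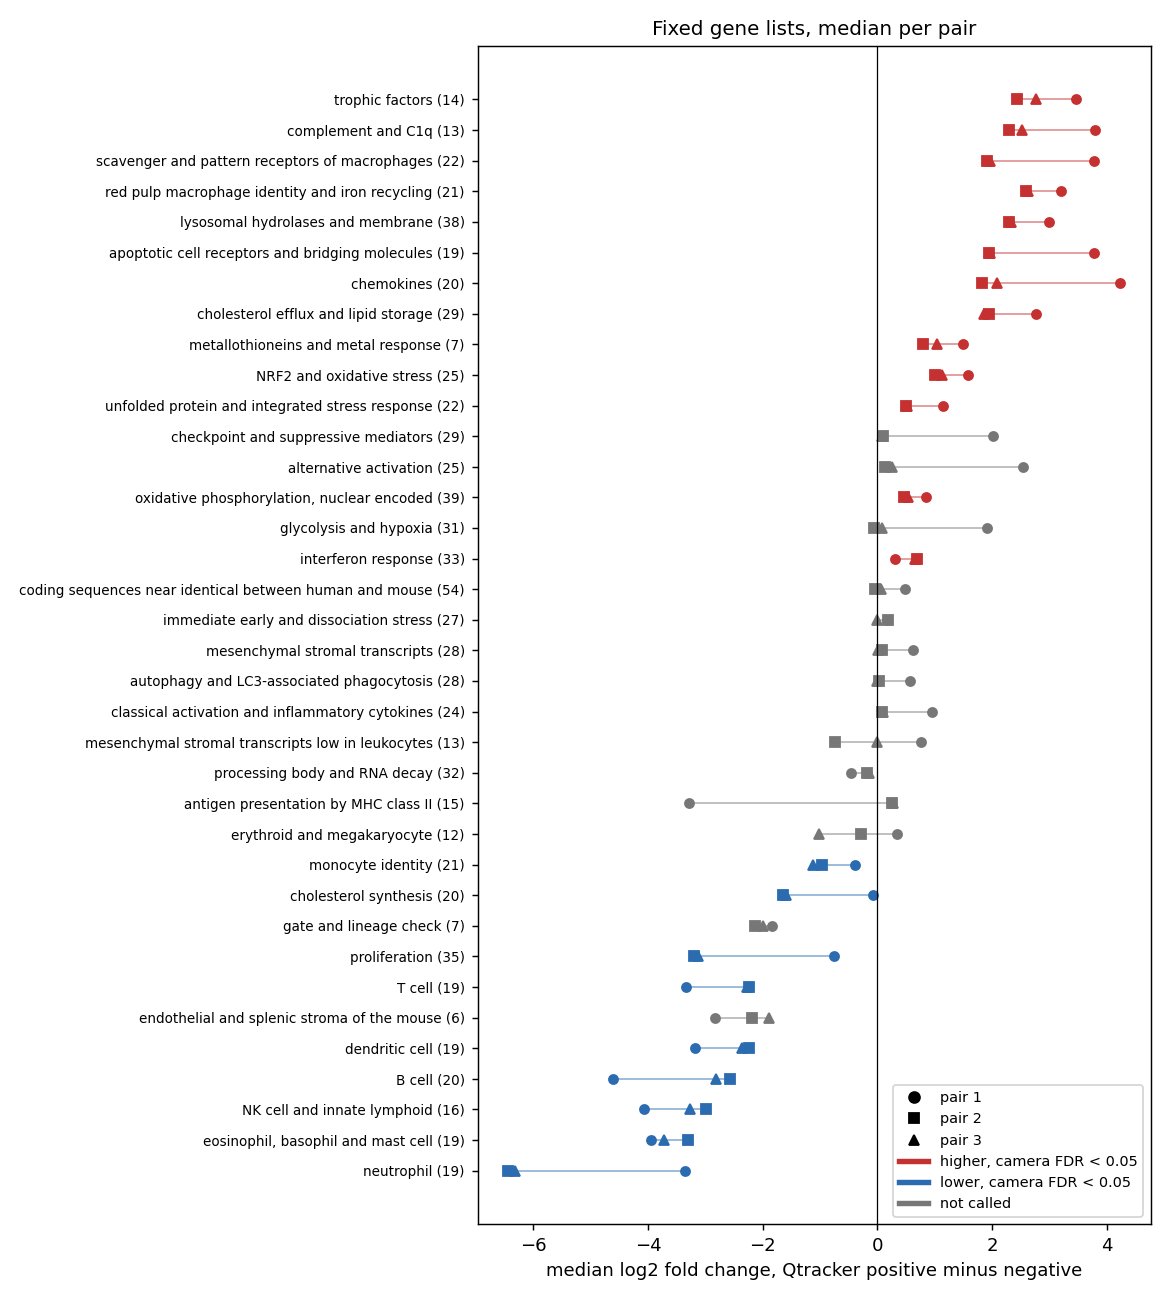
Median log2 fold change (Qtracker positive minus negative) over the measured members of each of 36 gene lists, with 1 symbol per pair and the number of measured members in parentheses. Colours mark the 13 lists higher and the 9 lower by camera with its preset correlation, of which 0 were called with an estimated correlation, and pair 1 often lies apart from pairs 2 and 3.

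Activation genes did not move together. In the alternative activation list 8 of 25 members rose and 7 fell (9 and 7 adjusted over the list alone), and it was not called (camera adjusted p = 0.414), with a median of 2.53 in pair 1, 0.13 in pair 2 and 0.25 in pair 3. Arg1, or arginase, rose from 61.5 ± 33.7 to 1530 ± 2081 CPM (SD, n = 3), with 3933 CPM in Qtracker positive replicate 1 against 317.1 and 340.6 CPM in replicates 2 and 3. Of 24 classical activation and inflammatory cytokine genes 6 rose, including Il1a (4.90 ± 0.27), and 5 fell, including the cytokine chain Il12b (-3.11 ± 0.23), or 6 and 6 adjusted over the list alone. That list was not called (adjusted p = 0.757), and its median of 0.05 and mean of -0.01 had opposite signs. Its median also turned to -0.10 with upper quartile factors and -0.30 with library totals. Of 29 checkpoint and suppressive genes 8 rose and 5 fell (11 and 5 adjusted over the list alone). The list was not called (adjusted p = 0.196), but was higher without replicate 1 (6.2e-05), 2 (0.0209) or 3 (0.0192). It was also higher with library totals alone (0.0238) and by DESeq2 (0.0259). Without replicate 1 its median was only 0.1032, with 14 members higher and 13 lower, and over pairs 1, 2 and 3 its median was 2.01, 0.10 and 0.08. Cd274, which encodes PD-L1, rose from 67.8 ± 28.8 to 329 ± 176 CPM, and the ectonucleotidase Entpd1 rose by 1.76 ± 0.14. Il10 (-2.05 ± 0.86, adjusted p = 0.139) and Il1rn (0.83 ± 0.92, adjusted p = 0.511) did not pass the test, and the Il10 call was reached without replicate 1 (adjusted p = 0.00971) and by DESeq2 (0.0241).

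Of 20 chemokines 8 rose and 2 fell (13 and 2 adjusted over the list alone), with camera adjusted p = 0.000319 (adjusted p = 0.579 with an estimated correlation) and a median of 4.23 in pair 1, 1.82 in pair 2 and 2.09 in pair 3. Ccl8, with 2 negative libraries at 0, averaged 3.3 ± 3.99 CPM in positive libraries, so its fitted change depends on the prior count. Ccl5 fell by 3.21 ± 0.37. Of 33 interferon response genes 6 rose and 2 fell (2 and 2 adjusted over the list alone), with Bst2 at 2.56 ± 0.16 and Cmpk2 at -1.63 ± 0.25. The share that rose was close to that of all genes (2707 of 14605). The list was higher by camera (adjusted p = 0.0261; adjusted p = 0.567 with an estimated correlation), a call lost without the replicate block (0.0639) and with the stricter filter (0.0618). In the MHC class II list 2 of 15 genes rose, including the protease Ctss (3.17 ± 0.35), and 3 fell, including H2-DMb2 (-3.21 ± 0.46) (3 and 4 adjusted over the list alone), and it was not called (adjusted p = 0.414). Its median was -3.28 in pair 1, 0.26 in pair 2 and 0.27 in pair 3. The B cell list likewise fell most in pair 1 (-4.61, against -2.57 and -2.82). H2-DMb2 stood at 487 CPM in Qtracker negative replicate 1 and at 159 and 168 CPM in replicates 2 and 3.

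Oxidative stress and metal genes were higher. Of 25 NRF2 and oxidative stress genes 13 rose and 0 fell, also adjusted over the list alone. They included the peroxide reducing enzyme Prdx1 (3.78 ± 0.19) and Srxn1 (3.32 ± 0.14). The list had camera adjusted p = 3e-05 (adjusted p = 0.567 with an estimated correlation). Of 7 metallothionein and metal genes 4 rose and 1 fell, also adjusted over the list alone. The metal binding proteins Mt1 and Mt2 rose from 29.2 ± 6.86 to 299.9 ± 10.7 CPM and from 0.723 ± 0.429 to 11.6 ± 4.55 CPM, and the zinc exporter Slc30a1 by 2.14 ± 0.11. That list had camera adjusted p = 0.0363 (adjusted p = 0.567 with an estimated correlation), and lost its call with the stricter filter (0.0615), limma-voom (0.0515) and the authors' normalized counts (0.076).

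Of 39 nuclear oxidative phosphorylation genes 17 rose and 0 fell (30 adjusted over the list alone), by small amounts such as Sdhc at 1.25 ± 0.15 and Ndufa5 at 0.98 ± 0.12 (camera adjusted p = 1.56e-06; adjusted p = 0.615 with an estimated correlation). Of 22 unfolded protein and integrated stress genes 10 rose and 1 fell, also adjusted over the list alone, including Atf3 (3.45 ± 0.28) and the chaperone Canx (1.36 ± 0.15), with camera adjusted p = 0.000725 (adjusted p = 0.672 with an estimated correlation). Of 35 proliferation genes 16 fell and 0 rose (18 adjusted over the list alone), or 33 and 1 without replicate 1, including the replication helicase subunit Mcm4 (-1.52 ± 0.11) and the centromere histone Cenpa (-1.90 ± 0.15), with camera adjusted p = 3.54e-07 (adjusted p = 0.615 with an estimated correlation). Their median was -0.76 in pair 1, -3.19 in pair 2 and -3.13 in pair 3, and the neutrophil list likewise fell less in pair 1 (-3.36) than in pairs 2 and 3 (-6.44 and -6.32). Autophagy genes were not called as a list (8 of 28 higher and 0 lower, also adjusted over the list alone, adjusted p = 0.18), but were by DESeq2 (0.0301). Without replicate 1, 10 were higher and 9 lower, and the median of 0.08 turned negative with upper quartile factors (-0.06) and library totals (-0.26). Gabarapl1 (2.34 ± 0.12) and Sqstm1 (2.16 ± 0.16) rose. Glycolysis and hypoxia genes split, with 6 of 31 higher, including P4ha1 (2.35 ± 0.28), and 2 lower, including the glucose transporter Slc2a3 (-5.26 ± 0.57), also adjusted over the list alone. That list was not called (adjusted p = 0.0913), but was higher in 7 alternatives (0.0182 to 0.0487), among them without replicate 2 (0.0217) and without replicate 3 (0.0237). Its median was 1.90 in pair 1, -0.07 in pair 2 and 0.07 in pair 3. Immediate early genes split as 5 higher and 5 lower of 27, also adjusted over the list alone (adjusted p = 0.727), with Egr2 at 1.98 ± 0.25, and their median of 0.15 became -0.19 with library totals.

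Of 32 processing body and RNA decay genes 1 rose and 5 fell (1 and 4 adjusted over the list alone), and the list was not called (adjusted p = 0.0652), but was lower in 5 alternatives (0.0167 to 0.0339), among them the stricter filter (0.0194). Ddx6, a processing body helicase, fell from 134 ± 13.9 to 65.3 ± 7.16 CPM, Nanos1 fell by 3.53 and Tnrc6b by 1.69 on the log2 scale. Genes characteristic of stromal cells were not called as a list (4 of 28 higher and 3 lower, also adjusted over the list alone, adjusted p = 0.727), with Lgals1 (3.04 ± 0.25) higher. The subset low in leukocytes had 1 higher, Cav1 (3.78 ± 0.53), and 2 lower, including Col5a1 (-5.49 ± 0.77), of 13, also adjusted over the list alone, and a median of -0.10 (adjusted p = 0.932). Col1a1, the main collagen of stromal cells, stood at 2.58 ± 1.54 CPM in negative and 2.09 ± 0.326 CPM in positive libraries and did not pass (adjusted p = 0.917, and 0.0153 without replicate 1). Among 54 genes with coding sequences nearly identical in human and mouse, which human reads could reach, 9 rose, including Arf4 (0.91 ± 0.11) and Calm2 (1.43 ± 0.18), and 4 fell (6 and 1 adjusted over the list alone), and the list was not called (adjusted p = 0.26). Its median of 0.17 became -0.18 with library totals.

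The counts of called members above often depended on replicate 1. So did the calls over all genes, which were 10890 of 14932 tested without it and 5091 of 14605 with all libraries. Those numbers are the background for the list counts given here and above without replicate 1. Without it, the members higher and lower, in that order, were 19 and 3 for scavenger receptors, 11 and 2 for complement, 21 and 7 for cholesterol efflux and lipid storage, 13 and 12 for alternative activation, 11 and 10 for classical activation, 16 and 2 for chemokines, 23 and 6 for interferon response, 9 and 6 for MHC class II, 12 and 2 for trophic factors, 16 and 3 for red pulp macrophage identity and iron recycling, 6 and 13 for monocytes, 18 and 5 for oxidative stress, 5 and 2 for metallothioneins and metal response, 14 and 11 for glycolysis, 36 and 0 for oxidative phosphorylation, 18 and 4 for unfolded protein stress, 7 and 16 for processing bodies, 12 and 9 for immediate early genes, 9 and 9 for stromal genes, 2 and 4 for stromal genes low in leukocytes, 24 and 22 for near-identical coding sequences, 2 and 15 for T cell, 6 and 11 for dendritic cell, 3 and 7 for erythroid and megakaryocyte genes and 1 and 5 for endothelial and splenic stroma genes, each with at least 1 of its counts over 1.5 times that with all libraries.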

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

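Among the main calls that a setting also tested, 100% kept their direction, except 99.96% with the authors' normalized counts, but the number of calls was not kept. The stricter filter tested 12224 genes. The setting with replicates 2 and 3 summed was chosen after seeing the data, and the others before the data were examined. With library totals alone, genes higher fell to 1572 and those at least 2-fold higher to 1120, while the median of all tested genes moved to -0.357, and with upper quartile factors it moved to -0.152 and 45% of calls were higher. With DESeq2, genes lower numbered 3702 and those at least 2-fold lower 2967. Leaving out each replicate in turn gave 0 to 5538 genes higher, 0 to 5352 lower, 0 to 2130 at least 2-fold higher, 0 to 3114 at least 2-fold lower, 14 to 15 lists higher and 6 to 10 lists lower. The gene counts were lowest without replicate 3 and highest without replicate 1, and the list counts were lowest without replicate 1. With replicates 2 and 3 summed, all 4 gene counts were 0 by edgeR, with 4488 genes at an unadjusted p under 0.05, 3543 called by DESeq2 and 1405 by limma-voom. With an estimated correlation, 0 lists were higher and 0 lower, a version that can call little with 6 libraries. Without the replicate block, 2911 genes were higher and 3058 lower, 1779 and 2482 by at least 2-fold, with 13 lists higher and 9 lower, and the calls of Ly6c2, C4b, Gzmb and the interferon list were lost while the glycolysis list was called (0.0471). The cause of these shifts was not tested. None of the named genes and fixed lists that had a call changed sign (for lists, the camera direction) in the settings that tested them. These settings reuse the same libraries. Of the genes called higher 2706, and of those called lower 2381, already moved alike in all 3 pairs. A kept direction is therefore little further support. The stricter filter tested 88 of the 91 named genes. Depth limits the lowest genes, such as Ccl8, with 2 libraries at 0.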

Other observations

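Some gene families were picked by symbol after the fold changes had been seen, and their members were counted without a test of each family as a whole. Of 183 immunoglobulin segments and constant regions 167 fell and 0 rose, with a median log2 fold change of -4.26, though reads can be shared between segments. Of 46 replication-dependent histones 18 fell, with a median of -2.39. Of 40 proteasome subunits 20 rose and 2 fell (median 0.62) and of 76 mitochondrial ribosomal proteins 25 rose and 0 fell (0.50), or 9 higher in each of these families with library totals alone (medians 0.274 and 0.147). Of 17 vacuolar ATPase subunits, which acidify lysosomes, 10 rose and 1 fell (1.43). Of 77 cytosolic ribosomal proteins 9 fell and 0 rose (-0.39), against 2384 lower of all 14605 genes, and with library totals alone 34 fell, against 3316 of all genes. Of 9 plexins, receptors for semaphorins, 6 rose (2.70). No family median changed sign under the other scalings.

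The tests of the explanations below were chosen after the fold changes were seen, except the counts over other splits of the libraries. The higher macrophage, lysosome and lipid genes could come from dilution, if the same phagocytes were mixed with more lymphocytes and granulocytes in the negative libraries. Under dilution, the genes of the lysosomal, lipid handling and trophic lists should rise by no more than genes limited to mononuclear phagocytes, 10 of which were measured and were chosen after their fold changes had been seen. The median of all 38 measured lysosomal genes exceeded that of the 10 by -0.039 ± 0.764 (mean and SD over 3 pairs), and that of all 43 measured lipid handling and trophic genes by -0.0464 ± 0.509. Both differences were below 0 in pair 1 and above 0 in pairs 2 and 3, so dilution stays open for both groups of genes. This version was chosen after 2 others, limited to called members, had been seen. Those gave -0.0651 ± 0.326 and 0.251 ± 0.498 for lysosomal genes, and 0.593 ± 0.421 and 0.909 ± 0.591 for lipid handling and trophic genes, above 0 in each pair. They select genes by the change itself and were not used to decide.

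A larger share of monocytes in the negative libraries could add to the same pattern and stays open. The monocyte list was lower by camera with its preset correlation, with a median of -1.15 and 8 of 21 members lower and 1 higher. The loss of its call with an estimated correlation does not decide, since 0 of 36 lists were called there. Human stromal RNA counted on mouse genes was argued against as the source of these rises as a whole. Such RNA would bring the abundant collagen and matrix transcripts of stromal cells, yet 29 stromal genes low in leukocytes together stood at 16.2, 16.3 and 15.4 CPM in Qtracker positive replicates 1, 2 and 3. That is at most 0.0112% of the summed rise of the 81 lysosomal, lipid handling and trophic genes (145919 to 151016 CPM over the pairs). The test takes it that human reads reach stromal genes about as readily as the others, which was not tested, and a part of single rises stays open. In the negative libraries the stromal sum was 11.6, 41.4 and 40.3 CPM. A response to engulfment itself, and to the metal in the quantum dots for Mt1, Mt2 and Slc30a1, cannot be separated from the sort by these data and was not tested.

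Of 74 measured markers of B cells, NK cells, T cells and neutrophils, 59 were lower in Qtracker positive libraries and 1 higher, which is consistent with more of these cells in the negative libraries. The most abundant neutrophil marker was S100a9 (15063 ± 12093 CPM negative, 172 ± 67.9 CPM positive; SD, n = 3) and the most abundant B cell marker Ighm (7720 ± 4046 and 494 ± 33.8 CPM). S100a9 and Ighm were picked after their values were seen. A CD11b and Ly6G gate would be meant to remove most of these cells, and the splenocytes added had been depleted of T cells. Of the 74 markers, 5 also stood on another list, and 41 averaged at least 1 CPM in Qtracker positive libraries.

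Replicates 2 and 3 were nearly alike in each group. A repeated deposit of the same library was argued against by a variance 1.66 times that of counting in the negative group, the lower of both groups. Shared cells, day or RNA for replicates 2 and 3 was not tested and would make the p-values too small.

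In the 10 splits of the 6 libraries, the real split called 5091 genes and 3625 at least 2-fold, 1 split of 10 in each case, and the highest other split called 0. For lists, 5 of the 10 splits called at least as many as the real 22, and the highest other called 27. Among the 4 splits that part all 3 pairs, list calls were 22, 27, 22 and 5. With 10 splits no share under 0.05 can be reached. Each of the other splits puts 2 libraries of one group with 1 of the other. Of these, a split that parts only 1 pair takes the group difference of that pair as its contrast. One that parts all 3 keeps part of the group difference. The rest of that difference enters the residual spread, which holds down gene calls. So neither the 0 gene calls nor these list counts give a level expected without a change.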
